A study of Mus musculus with 12 samples.

How the data were processed

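DNA methylation was measured in 12 libraries of mouse bone marrow cells sorted as LSK, a fraction that lacks lineage markers, carries Sca1 and cKit, and holds the blood stem and early progenitor cells. The animals were C57BL/6 and 6 months old, per the labels. The labels put 3 libraries in each of 4 groups: Nras G12D (an activating mutation of the signalling GTPase Nras), Tet2 knockout (loss of Tet2, an enzyme that oxidises methylcytosine), and both changes together in animals without and with leukemia. The group with leukemia was read from the prefix L in the titles and from the series design, and its libraries are called "labelled leukemic" here. Wild-type libraries, which the series design names, were not analysed here, so genotypes were compared with each other only. The labels do not say whether the replicates of a group were separate animals in every case, so p-values measure the spread between these libraries.

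The libraries were made by reduced representation bisulfite sequencing, per the labels' protocols: DNA was cut with MspI, fragments of 150 to 400 bp were selected, converted with bisulfite, amplified by PCR and read for 50 bp from a single end. Bismark and the mouse build mm9 (NCBIM37) are named in the submitters' processing notes, without a version for Bismark. The deposited tables list each CpG position and strand with its coverage, a count of reads, and the percent of reads with C (methylated) and with T (unmethylated). Every position listed in the deposited tables has a coverage of at least 10 reads. Methylated and unmethylated read counts were computed from coverage and percent and rounded to whole reads. Reads with another base, present at 1.09% to 2.74% of the positions of a library, were left out. No molecular identifiers are named in the sources, so PCR copies count as reads, and coverage overstates the number of molecules behind a value.

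The tables held 2615441 strand positions on the autosomes and the X, Y and mitochondrial chromosomes, and libraries summed to 96300485 to 199736369 reads over listed cytosines. The strands of a CpG were added to 1 CpG dyad. Tests used the 916889 autosomal dyads with at least 10 reads in every library, leaving out dyads above the 99.9th percentile of coverage of a library. Their median coverage was 70 to 146 reads. Mitochondrial CpGs read as methylated at 0.222% to 1.00% per library. Regions were non-overlapping tiles of 1000 bp with at least 3 tested dyads, 81049 in all, with a median of 5 dyads. The gene table at hand is of another mouse assembly (GRCm38.p6), so its coordinates were not used. Promoter regions, the fixed gene lists and the check of the Tet2 and Nras genes were therefore not run, and regions are given by their mm9 coordinates.

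Each dyad or tile was tested with a quasi-binomial model of methylated and unmethylated reads on the group, over all 12 libraries with 8 residual degrees of freedom. The Pearson dispersion was moderated across CpGs or tiles with the method of limma's squeezeVar and floored at 1, and each of 6 contrasts was an F test of the deviance difference with Benjamini-Hochberg adjustment. A CpG was called at an adjusted p under 0.05 and a difference of group means of at least 25 percentage points, a tile at an adjusted p under 0.05 and at least 10 points. The mean methylation of each library over the tested dyads was compared between groups with a two-sided exact permutation test, in which 3 libraries against 3 cannot give a p below 0.1. It was also taken over dyads with a mean over all libraries under 20%, of 20 to 80%, and over 80%. Named tiles followed a rule: per main contrast, the 5 called tiles with the largest rise and the 5 with the largest fall among those with at least 5 dyads and no overlap between the replicates of the groups. The main contrasts were the 3 among the groups not labelled leukemic and the leukemic against the nonleukemic double mutant. Alternatives were another coverage minimum (20), no high-coverage filter, separate strands, the X chromosome, other effect sizes, other tiles, limma on log2((methylated + 1)/(unmethylated + 1)), Fisher's exact test on pooled reads, a fit on the groups compared, a replicate block, equal coverage by thinning, and each replicate left out. These and the tests were chosen before the data were examined. A fit without the leukemic group, and fits without chromosome 3, without 3 libraries with single-library flips and without 3 libraries with Y chromosome reads were added after the data had been seen. A flip is a strand position under 10% in 1 library and over 70% in the 11 others, or the reverse. The fit without flips left out Nras G12D replicate 3, Tet2 knockout replicate 2 and leukemic replicate 3, the library with the most flips in each group where that number was above 100. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, numba 0.67.0, R 4.3.3 and limma 3.58.1 were used.

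The tests were tested on simulated data with each library's own spread and 200 changed CpGs or tiles among those over 80%. For Tet2 knockout against Nras G12D, with 916889 CpGs, a fall of 30 points was recovered at 0% of 67 CpGs and a fall of 70 points at 7.58% of 66 CpGs. Over the 81049 tiles of that contrast, a fall of 15 points was recovered at 2.99%, of 30 points at 17.9% and of 50 points at 65.2% of the changed tiles, with 0 unchanged tiles called. For the libraries labelled leukemic against the nonleukemic double mutant, falls of 30 and 50 points were recovered at 26.9% and 68.2% of the changed tiles, and 13 of the 77 tiles called were unchanged. Falls of 30, 50 and 70 points were recovered at 1.49%, 4.48% and 18.2% of the changed CpGs of that contrast, and 4 of the 20 CpGs called were unchanged. All groups share 1 spread estimate, so calls of the leukemic libraries can include false ones, as in this simulation. For the same reason, differences among the other groups can be missed. Replicates were compared before averaging: over partly methylated dyads, the mean chi-square of a replicate pair was 4.93 to 29.5, where read sampling alone gives 1. PCR copies raise this value too, so it does not show whether the libraries came from separate animals.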

Results

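CpG methylation was measured in LSK cells, the stem and progenitor fraction of the bone marrow, from mice with activated Nras, with loss of Tet2, or with both. The 12 libraries fall into 4 groups of 3: Nras G12D, Tet2 knockout, nonleukemic double mutant and double mutant labelled leukemic. The Nras G12D libraries held 107032660, 126695756 and 116992281 reads over listed cytosines, and the Tet2 knockout libraries 122263670, 96300485 and 120086645. The nonleukemic double mutants held 115818046, 129362137 and 119498739 reads, and the libraries labelled leukemic 199736369, 133069618 and 141497141. Median coverage of the tested CpGs ran from 70 to 146 reads.

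The first question was how the level of methylation differs between the genotypes and with leukemia. Mean methylation over the 916889 tested CpGs was 33.4% ± 0.204 (SD, n = 3) in Nras G12D, 34.2% ± 0.260 (SD, n = 3) in Tet2 knockout and 33.8% ± 0.0601 (SD, n = 3) in the nonleukemic double mutant. The libraries labelled leukemic had the lowest level, 31.5% ± 0.675 (SD, n = 3). The 68407 partly methylated CpGs, with a mean of 20 to 80% over all libraries, differed by more points than the other classes, with means of 54.9% ± 0.200 in Nras G12D, 59.5% ± 1.62 in Tet2 knockout, 57.8% ± 0.364 in the nonleukemic double mutant and 46.7% ± 1.61 in the libraries labelled leukemic (SD, n = 3 each). At the 278731 CpGs with a mean over 80%, the leukemic libraries were at 89.7% ± 1.93 and the other groups between 94.2% and 95.3%. At CpGs with a mean under 20%, all 4 groups lay between 1.08% and 1.27%. These classes use the leukemic libraries too, so a fall there can itself move CpGs between classes. With classes set on Nras G12D alone, leukemic minus nonleukemic was -8.88 points at 20 to 80% and -5.60 points over 80%. Against Nras G12D, the leukemic libraries were then at 50.1% against 54.5% and at 88.8% against 94.6%. That difference was larger over 80%, but classes set on the Nras G12D libraries bring regression to the mean into it. With classes set on all libraries, leukemic minus Nras G12D was -8.24 points at 20 to 80% and -4.55 points over 80%.

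No library of 1 group overlapped with a library of another in the mean over all tested CpGs. Each of the 6 pairs of groups reached an exact permutation p of 0.1 there, the smallest that 3 against 3 libraries allow, and 0.1 after adjustment over the pairs. With CpGs weighted by coverage, the differences were 3.33 points for Tet2 knockout minus Nras G12D (0.781 unweighted), -2.72 for the nonleukemic double mutant minus Tet2 knockout (-0.356) and 0.614 for it minus Nras G12D (0.425, exact permutation p = 0.4 when weighted). The weighted leukemic differences were -3.70 from the nonleukemic double mutant, -6.42 from Tet2 knockout and -3.08 from Nras G12D (unweighted -2.38, -2.74 and -1.96). Under 20% methylation the groups overlapped, with exact permutation p from 0.2 to 0.6.

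**Figure D1:**
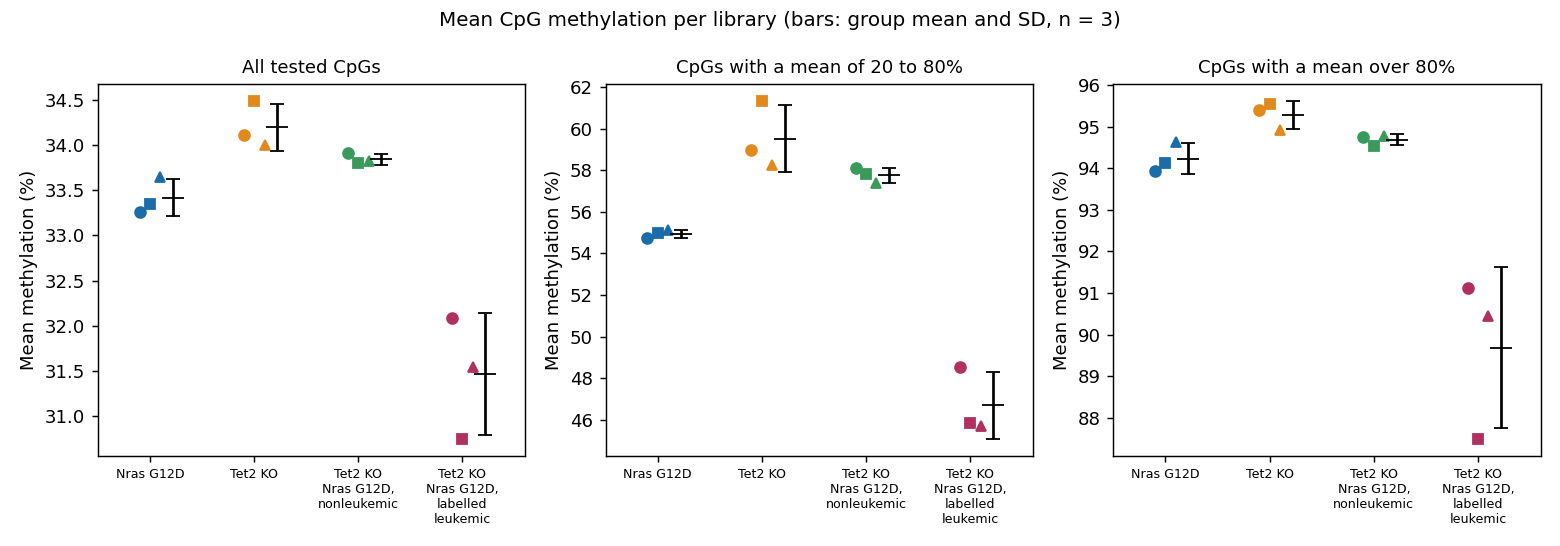
Mean CpG methylation in percent (vertical axes, not starting at 0) of each library by group, with circles, squares and triangles for replicates 1, 2 and 3 and black bars for the group mean and SD (n = 3). The libraries labelled leukemic lie below the others in each panel, between 30.7% and 32.1% over all tested CpGs.

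Tet2 loss was compared with Nras activation directly. The 5 CpGs called, all lower in Tet2 knockout, lie on chromosome 3, the chromosome of both Tet2 and Nras. They are at positions 130530764, 133611402, 137777111, 137785715 and 139484859 (mm9), and with 5 calls they are named here after their values were seen. At each, the Tet2 knockout libraries were at 0% to 2.5% and the Nras G12D libraries at 84.5% to 100%, a median difference of -97.1 points, with adjusted p from 0.000705 to 0.018 in the quasi-binomial model and 15 to 175 reads per library. The libraries labelled leukemic were at 86.7% to 100% at these CpGs, like Nras G12D, and the nonleukemic double mutants at 0% to 4.05%, like Tet2 knockout. No tile was called, and none in limma. The quasi-binomial model gave an unadjusted p under 0.05 at 4046 tiles higher and 728 lower in Tet2 knockout, where 4052 are expected by chance in all, and limma at 3904 and 934. The CpG calls fell to 0 in a fit on the 6 libraries of these groups and without the 3 libraries with Y chromosome reads, and to 3 without Tet2 knockout replicate 2. Without Tet2 knockout replicate 1 and 2 in turn, 1 and 2 tiles were called, and a fit without the leukemic group called 14.

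Adding Nras G12D to Tet2 loss was read from the nonleukemic double mutant against Tet2 knockout. Methylation of the double mutant differed by -0.356 points over all tested CpGs and by -1.76 points at partly methylated CpGs, with no overlap between the replicates. No CpG and no tile was called in the quasi-binomial model or in limma. At an unadjusted p under 0.05, the quasi-binomial model gave 783 tiles higher and 1928 lower, and limma 978 and 2261. By chance 4052 tiles are expected in all, more than either gave. The spread estimate of both tests takes in the leukemic libraries, whose replicate pairs had a mean chi-square of 17.3 to 29.5. Pairs of the nonleukemic group had 4.93 to 5.28, and those of Tet2 knockout 8.66 to 16.9. The p-values here can therefore be too large, so a count below chance does not show that these groups are alike. Single CpGs reached an unadjusted p under 0.05 in the quasi-binomial model at 25408 sites higher and 30249 lower, where 45844.5 are expected in all. Without nonleukemic replicate 3, 3 CpGs and 4 tiles were called.

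Adding Tet2 loss to Nras G12D was read from the nonleukemic double mutant against Nras G12D. In 4 tiles the double mutant was called more methylated. The tile of chromosome 6 from 116601000 to 116601999 (10 CpGs, 859 to 1983 reads per library) was at 63.0% ± 17.4 (SD, n = 3) against 10.9% ± 4.95 (SD, n = 3), adjusted p = 0.0109 in the quasi-binomial model with limma's moderation. The other 3 tiles were close to unmethylated in Nras G12D and at 20.2% to 21.1% in the double mutant: chromosome 12 from 20927000 to 20927999 (12 CpGs), chromosome 6 from 81915000 to 81915999 (20 CpGs) and chromosome 8 from 42219000 to 42219999 (17 CpGs). Their differences were 20.9, 19.9 and 19.8 points, and that of the chromosome 8 tile was 6.37 points, with adjusted p = 1, at a coverage minimum of 20. Calls were lost in 7, 6, 8 and 11 of 16 alternatives for the 4 tiles in the order given, and without nonleukemic replicate 2 the tiles at 81915000 and 42219000 had adjusted p = 0.0961 and 0.139. Positions covered in the nonleukemic libraries only lay within 1 Mb of the tile at 116601000 (7 positions) and of the tile at 42219000 (2 positions), and of neither other tile. In Tet2 knockout these 4 tiles were at 17%, 8.06%, 4.05% and 0.603%, and in the libraries labelled leukemic at 10.7%, 0.0700%, 0.228% and 0.876%. The 7 CpGs called were all lower in the double mutant, 6 of them on chromosome 3 and 1 on chromosome 8 at position 71929002, with a difference of -75.4 points, adjusted p = 0.0379 and 42 to 166 reads per library. Near the latter CpG, position 71929035 was covered in the nonleukemic libraries only. With chromosome 3 left out, that CpG was no longer called. Tile calls numbered 132 in a fit on the 6 libraries of these groups. They numbered 0 in limma, with the replicate number as a block, without any 1 of the Nras G12D libraries and without nonleukemic replicate 1. There were 4 CpG calls without nonleukemic replicate 1 or 2 or without Nras G12D replicate 2. With the block there were 2, and without the 3 libraries with Y chromosome reads 0.

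Of the CpGs called in the comparisons of Tet2 knockout and of the nonleukemic double mutant with Nras G12D, 5 were shared, all lower, where independent lists give 3.82e-05. Simulated unchanged groups against the same Nras G12D libraries shared 0. The covariance of the differences across CpGs was 17.6 squared points, and 13.4 in the simulation. The 3 Nras G12D libraries could not be parted into sets of at least 2 libraries here, so part of the excess covariance may come from these shared libraries. At the 5 shared CpGs the libraries labelled leukemic, which belong to neither comparison, were also high, at 86.7% to 100%. This argues against the shared libraries as the source of that overlap. These CpGs lie on chromosome 3 and may be inherited sequence variants, so the overlap does not show a shared effect of Tet2 loss on methylation.

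Leukemia was addressed by comparing the libraries labelled leukemic with the nonleukemic double mutant. At the called CpGs of chromosome 3, the leukemic libraries were like Nras G12D and the nonleukemic ones like Tet2 knockout. These groups may thus differ in genotype or inherited sequence as well as in leukemia, which this contrast cannot tell apart. Of the 81049 tiles, 3459 were lower and 99 higher in the leukemic libraries, with a median difference of -20.7 points among the lower and 21.8 among the higher ones. The lower tiles were 5.72% of the tiles over 80% in the nonleukemic group, 8.52% of those at 20 to 80%, and 0.153% of those under 20%. They were spread over all autosomes, 3.52% of the tiles of chromosome 14 and 4.75% of those of chromosome 15 being the lowest and highest shares. The replicates did not overlap in 3356 of the lower tiles, and in 22.4% of all tiles, where chance gives 10%. At single CpGs, 1100 were lower and 42 higher. Without the 3 libraries with Y chromosome reads, of which nonleukemic replicate 1 is in this comparison, 0 CpGs and 558 tiles were called. In simulated data for this comparison, 13 of 77 tile calls and 4 of 20 CpG calls were at unchanged tiles or CpGs.

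Among called tiles with at least 5 CpGs and no overlap between the replicates, the largest fall was on chromosome 8 from 35160000 to 35160999 (6 CpGs, up to 673 reads per library), at 93.6% ± 1.03 in the nonleukemic double mutant and 17.7% ± 27.7 in the libraries labelled leukemic (SD, n = 3 each). Its call was lost in 6 of 14 alternatives, with adjusted p of 0.0681, 0.0543 and 0.0738 without nonleukemic replicate 1, 2 or 3. A tile of chromosome 16 from 30186000 to 30186999 (6 CpGs, 166 to 750 reads) fell from 79.9% ± 6.54 to 4.57% ± 5.19, with adjusted p = 1.95e-05 in the quasi-binomial model with limma's moderation. Nras G12D was at 54.4% ± 4.71 there and Tet2 knockout at 80.8% ± 0.714. On chromosome 8 from 125922000 to 125922999 (5 CpGs, 132 to 648 reads) methylation fell from 95.1% ± 2.22 to 22.3% ± 1.33. The remaining named falls are on chromosome 19 from 6284000 to 6284999 and on chromosome 4 from 133384000 to 133384999, with differences of -71.1 and -67.7 points.

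Among the tiles that rose, chromosome 15 from 82030000 to 82030999 (5 CpGs) went from 8.99% ± 4.2 to 42.6% ± 6.37 (SD, n = 3 each), and it was at 3.48% to 5.42% in the single mutants. Chromosome 11 from 115969000 to 115969999 rose by 34.7 points to 78.9% ± 3.76, and chromosome 10 from 82329000 to 82329999 by 34.8 points to 70.6% ± 18.2. The call of the chromosome 10 tile was lost in 9 of 14 alternatives, with adjusted p of 0.141, 0.127 and 0.138 without nonleukemic replicate 1, 2 or 3 and of 0.0813 and 0.0776 without leukemic replicate 1 or 2. Adjacent tiles of chromosome 4, from 116976000 to 116977999, rose by 32.7 and 33.3 points. In these adjacent tiles the Nras G12D libraries were at 76.2% and 76.4%, and the Tet2 knockout ones at 70.1% and 68.4%. The leukemic libraries were at 84.3% ± 2.53 and 75.9% ± 24.2, and the nonleukemic ones at 51.7% ± 13.0 and 42.7% ± 0.773. The nonleukemic mean was the lowest of all groups in both tiles, so the difference may lie in that group. In the tile from 116977000, leukemic replicate 1 was at 48.6%. The call of that tile was lost in 13 of 15 alternatives, with adjusted p of 0.145, 0.150 and 0.150 without nonleukemic replicate 1, 2 or 3 and of 0.0883 and 0.109 without leukemic replicate 2 or 3. The calls of this comparison depended on the test: all 10 named tiles lost their call in limma, with adjusted p from 0.0541 (chromosome 16) to 0.375 (chromosome 10). In all, limma called 45 tiles lower and 1 higher and 254 CpGs, and a fit on the 6 libraries of these groups 1104 and 44 tiles and 0 CpGs. Without nonleukemic replicate 1, 2 or 3, tile calls numbered 939, 830 and 966 and CpG calls 29, 14 and 50, and without leukemic replicate 1, 2 or 3 they numbered 6053, 3674 and 5178 and 3260, 2002 and 2663.

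**Figure D2:**
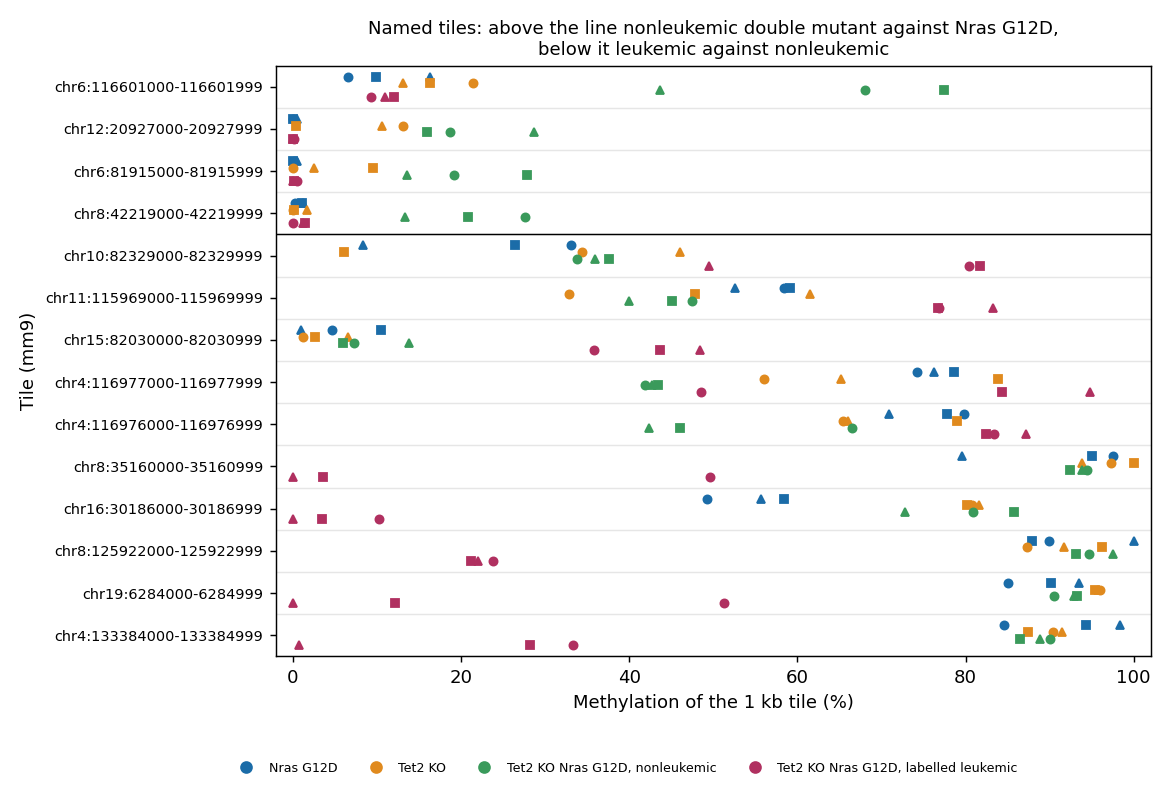
Methylation in percent (horizontal axis) of the 14 named 1 kb tiles in each of the 12 libraries, with groups in colour and replicates 1, 2 and 3 as circles, squares and triangles. Tiles above the black line were called between the nonleukemic double mutant and Nras G12D, those below it between the leukemic and the nonleukemic libraries, and in the 5 lowest tiles the leukemic libraries lie below all others.

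The libraries labelled leukemic were also set against each single mutant. Against Tet2 knockout, 2676 CpGs were lower and 78 higher, and 6484 tiles were lower and 134 higher. Against Nras G12D, 391 CpGs and 1796 tiles were lower, and 25 CpGs and 83 tiles were higher. The mean over all tested CpGs differed by -2.74 points from Tet2 knockout and by -1.96 points from Nras G12D. On 6 libraries alone neither comparison called a CpG, without the 3 libraries with Y chromosome reads they called 0 and 1, and limma called 1187 and 76 CpGs. Without replicate 1, 2 or 3 of Nras G12D, 18, 6 and 1 CpGs were called against that group, and of Tet2 knockout 1511, 463 and 446. Without leukemic replicate 1, 2 or 3, these counts were 2479, 1253 and 1807 against Nras G12D and 7108, 4709 and 6539 against Tet2 knockout.

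CpG positions covered in some groups and in no library of the others were not spread evenly over the genome. Of 216 positions with at least 20 reads in every Nras G12D and every leukemic library and listed in no other, 210 lie on chromosome 3, which holds 4.40% of the autosomal positions covered in all libraries. Of 166 positions covered in all Tet2 knockout and nonleukemic libraries only, 123 lie on chromosome 3. Most of the others lie on chromosome 4, from 48818537 to 63193785, so leaving out chromosome 3 does not leave out all such positions. Positions covered in the nonleukemic double mutants only numbered 378, with 280 on chromosome 8 and 58 on chromosome 6. No position was covered in the Tet2 knockout and leukemic libraries alone.

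**Figure D3:**
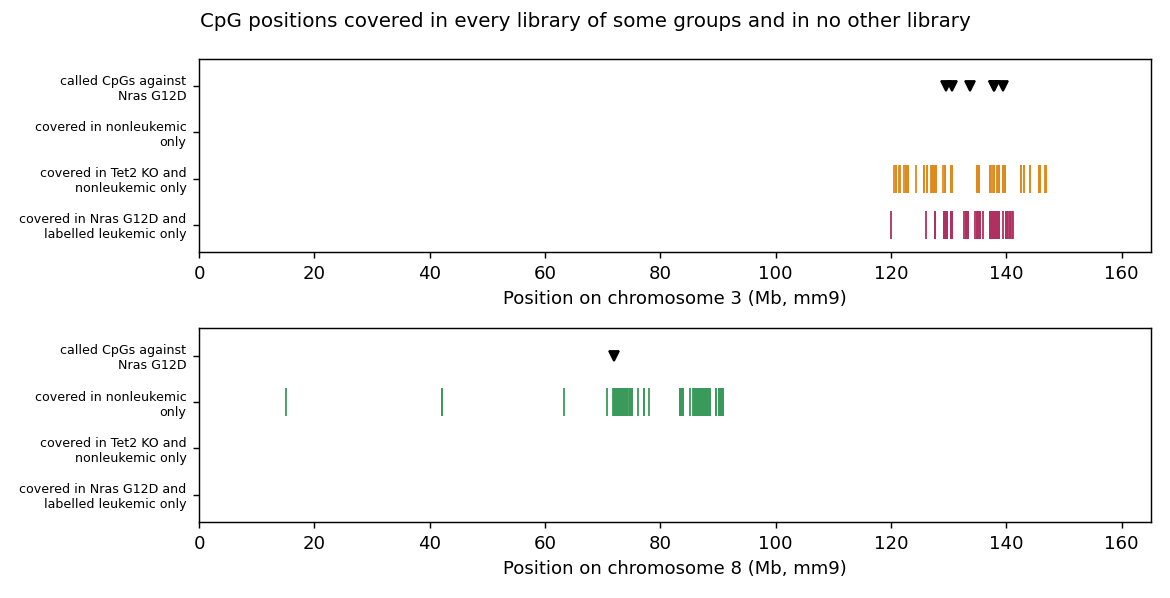
Positions on chromosomes 3 and 8 (horizontal axis, Mb, mm9) with at least 20 reads in every library of the groups named at the left and listed in no other library. Black triangles mark the CpGs called against Nras G12D, and the 6 on chromosome 3 lie within the stretch that holds the positions.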

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

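All tests of explanations below were chosen after the patterns had been seen. Signals outside the main measurement stood out at 210 positions of chromosome 3 covered only in the Nras G12D and leukemic libraries, 123 positions of chromosome 3 covered only in the Tet2 knockout and nonleukemic libraries, and 280 positions of chromosome 8 covered only in the nonleukemic libraries. Chromosome Y positions were listed for Tet2 knockout replicate 1 (360), Tet2 knockout replicate 2 (251) and nonleukemic replicate 1 (349), and 2 to 18 for each other library. Leukemic replicate 3 had 3118 single-library flips, positions under 10% there and over 70% in the 11 others or the reverse. Leukemic replicates 1 and 2 had 1005 and 79, and Tet2 knockout replicates 2 and 3 had 940 and 157. Nras G12D replicate 3 had 170, and the other 6 libraries had 0 to 2. Falls were 2967, 723 and 79 of the flips in leukemic replicates 3, 1 and 2. They were 294 and 83 in Tet2 knockout replicates 2 and 3, and 135 in Nras G12D replicate 3. Flips of the leukemic libraries can therefore include their lower methylation itself.

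The 6 CpGs of chromosome 3 called against Nras G12D may be sequence variants inherited with the Tet2 allele, since 97.2% of the positions covered only in Nras G12D and leukemic libraries lie on that chromosome. A methylation change of the surrounding region is argued against at 5 of them by the 22 tested CpGs within 1000 bp, which were at 86.1% to 100% in Nras G12D and differed in Tet2 knockout by a median of -3.26 points (range -17.1 to 11.7, lowest median around a called CpG -8.11). The CpG at 139484859 had 0 tested CpGs within 1000 bp, so a change of its surrounding region stays open. Of the 6 CpGs, 0 were under 50% in every leukemic library, and whether this comes from a label, from the origin of the allele or from recombination cannot be told apart, because no value here reads the Tet2 gene itself. Inherited variants stay open, untested, for the chromosome 8 CpG and for the tiles of chromosomes 6 and 8 near positions covered in the nonleukemic libraries only.

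Lower methylation in the libraries labelled leukemic was set against technical causes. Loss of methylated cytosines in conversion would lower partly and highly methylated CpGs by an equal fraction. Classes were set on Nras G12D alone for this test. From the nonleukemic group, the fall at the 67124 CpGs of 20 to 80% went beyond that fraction by -5.39 points (SD 1.46). That group lay above Nras G12D at these CpGs, at 59.0% against 54.5%. From Nras G12D, means went from 54.5% to 50.1% there and from 94.6% to 88.8% over 80%, nearer to an equal fraction. This baseline also set the classes, so regression to the mean enters its differences. The result at 20 to 80% depends on the baseline. At CpGs over 80%, the leukemic group was at 87.8% in tiles with 1 or 2 tested CpGs and at 89.9% with 25 or more. The nonleukemic group was at 94.5% and 93.2%, and Nras G12D at 94.7% and 94.0%. Each leukemic library was higher in the denser tiles, and each library of these other groups lower. This argues against an equal fraction lost as the whole account at CpGs over 80%. A share of conversion loss stays open. Leukemic replicate 2, with 79 flips, lay -2.51 points from the lowest of the 9 other libraries, and 1 library leaves few starting molecules open as a cause. Nras G12D alone, without Tet2 loss, is argued against as the whole account, since the highest leukemic library lay -1.17 points from the lowest Nras G12D library. This does not bear on whether Tet2 was lost in these libraries. Leukemia itself, a different mix of cells within the sorted fraction and a difference in genotype or inherited sequence, on chromosome 3 or elsewhere, stay open and untested.

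Higher methylation at partly methylated CpGs in Tet2 knockout and nonleukemic libraries than in Nras G12D was set against sex and library quality. The lowest of their libraries without Y reads lay 2.23 points above the highest Nras G12D library, and without the library with the most flips of each of 3 groups the gap was 2.41 points, both above the largest group SD of 1.62. Loss of Tet2 stays open, because the slopes across tiles given below cannot part it from a trait common to the Nras G12D libraries. Inherited variants elsewhere stay open and untested.

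With 10 splits of 6 libraries, no share under 0.05 can be reached. The real split called 5 CpGs for Tet2 knockout against Nras G12D (highest other split 0), 0 for the nonleukemic double mutant against Tet2 knockout (2), and 7 for it against Nras G12D (0). For the libraries labelled leukemic it called 1142 against the nonleukemic double mutant (0), 2754 against Tet2 knockout (15) and 416 against Nras G12D (0). The tile counts were 0 (highest other 0), 0 (1), 4 (0) and 3558 (1) for the main contrasts in the same order. As many calls as the real split came in 1 split, the real one, in 7 of the 10 results and in all 10 splits where the real count was 0.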

How the results depend on the processing

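Alternatives with libraries or chromosome 3 left out by Y reads, flips or group were chosen after the data had been seen. The direction of each global difference was kept in all 78 alternatives, and weighting by coverage moved Tet2 knockout minus Nras G12D from 0.781 to 3.33 points. Named tiles kept their sign in all 209 alternatives and lost their call in 68, among them the chromosome 8 tile at 42219000 with 6.37 points at coverage 20. CpG counts are given in the order Tet2 knockout minus Nras G12D (5), nonleukemic double mutant minus Tet2 knockout (0) and minus Nras G12D (7), then leukemic minus nonleukemic (1142), minus Tet2 knockout (2754) and minus Nras G12D (416). Fisher's exact test on pooled reads, which ignores the spread between replicates, gave 10515, 6163, 4576, 31972, 40500 and 30578, with most calls higher in the first (7688 of them) and in the third (3356), the reverse of the quasi-binomial calls. For the leukemic contrasts limma gave 254, 1187 and 76, and thinning to equal coverage 340, 1296 and 113, with 4 for the nonleukemic double mutant minus Nras G12D. On the 6 libraries compared, the first and the leukemic contrasts gave 0. Without chromosome 3 the contrasts called against Nras G12D gave 0, apart from the leukemic one. Without the library with the most flips of each of 3 groups all contrasts with Nras G12D gave 0, and leukemic minus Tet2 knockout 374. Without the 3 libraries with Y reads all gave 0 but leukemic minus Nras G12D (1), with 1 Tet2 knockout library left that is assumed to vary like the rest. Leaving out 1 replicate gave 3 to 5, 0 to 3, 4 to 8, 14 to 3260, 446 to 7108 and 1 to 2479 CpGs. Tile counts for Tet2 knockout minus Nras G12D (0) were 2 at coverage 20, 1 without the high-coverage filter, 3 in 500 bp tiles and 14 without the leukemic group. For the nonleukemic double mutant minus Tet2 knockout (0) the count was 2 without the high-coverage filter. For it minus Nras G12D (4) the counts were 0 in limma, 132 on 6 libraries and 7 without the leukemic group. For leukemic minus nonleukemic (3558) they were 1401 with at least 5 CpGs per tile, 46 in limma, 1148 on 6 libraries, 6534 without the library with the most flips of each of 3 groups and 558 without the Y libraries. Leaving out 1 replicate gave 0 to 2, 0 to 4, 0 to 6 and 830 to 6053 tiles. Replicate numbers did not pair the libraries: over 18 pairs with the same number, deviations from group means correlated at -0.00977 to 0.00786. With the replicate number as a block, the nonleukemic double mutant minus Nras G12D had 2 CpGs and 0 tiles, and other totals stayed within 1.5 times. Higher CpG calls of the leukemic contrasts went from 42, 78 and 25 to 129, 261 and 83 with the block. Promoter and gene list alternatives were not run. Beyond fewer samples, the cause was not tested.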

Other observations

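All tests here were chosen after the data had been seen. Some differences were smaller where CpGs were denser. At CpGs over 80% in Nras G12D, the libraries labelled leukemic differed from the nonleukemic double mutant by -6.71 points in tiles with 1 or 2 tested CpGs and by -3.30 points in tiles with 25 or more. At CpGs of 20 to 80% in Nras G12D, Tet2 knockout was 8.28 points above Nras G12D in tiles with 1 or 2 tested CpGs and 0.104 points above it in tiles with 25 or more. At CpGs over 80%, Tet2 knockout minus Nras G12D went from 0.536 to -0.717 points and the nonleukemic double mutant minus Nras G12D from -0.157 to -0.795 between the same tiles, so this does not hold for every comparison. The classes were set on the Nras G12D libraries, so the differences from Nras G12D include regression to the mean, which those between the double mutants do not.

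At 1368 strand positions that lay between 30% and 70% in each of the 9 other libraries, methylation was 44.4%, 41.2% and 41.4% in leukemic replicates 1, 2 and 3, against 48.4% to 51.3% in the others. The positions were chosen on those 9 libraries and not on the leukemic ones, so the unequal choice alone can set the groups apart. At 4202 positions of the X chromosome, with a mean under 5% in the libraries with Y reads and over 25% in Nras G12D, methylation was 30%, 27.9% and 26.6% in the leukemic replicates. Tet2 knockout replicate 3 was at 31.3% there and nonleukemic replicates 2 and 3 at 29.3% and 29.0%.

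A first hypothesis was that the nonleukemic double mutant shares a Tet2 effect with Tet2 knockout. For each of its libraries, the difference from a pair of Nras G12D libraries was regressed across 81049 tiles on the difference of Tet2 knockout from the remaining Nras G12D library, so that no library entered both sides. The 9 slopes ran from 0.0818 to 0.164, and from 0.0807 to 0.161 without chromosome 3, positive as a shared effect would give. Both sides are differences from Nras G12D libraries, so a trait common to the Nras G12D group would also give positive slopes. The sign therefore cannot tell a Tet2 effect from such a trait. The slopes share libraries and are not independent. A second hypothesis was that the libraries labelled leukemic share it too. Their 9 slopes ran from -0.206 to -0.0692. Their own loss of methylation at the same tiles may lower these slopes, so whether the effect is present there stays open.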
